A study of Bombyx mori with 4 samples.

How the data were processed

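Midgut RNA of silkworm larvae (Bombyx mori, day 2 of the fifth instar) was extracted with Trizol and sequenced after a standard Illumina library preparation, per the labels' protocols. There were 4 libraries, 1 for each of 932 control, 932 heat, HY control and HY heat, and each library was placed in its group by the variety and stress labels. The aligner, the counting tool, the filter on tags and the build of the gene models were not given in the sources used here. Per the file headers, the deposited values are normalized and called TPM, with 1 best protein hit for each gene model. The values behave as RPM: the deposited table gives tags per 1000000 tags of the library, and the authors made no correction for gene length that the values show.

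The unit was checked on the values. In each library the lowest value above 0 equals 2 tags, no value equals 1 tag, and 100% of the values are whole numbers of tags within 0.0051 RPM (the table has 2 decimals) at the library totals given in the report. At other totals near these, at most 26.0% of values were whole. A value listed at 0 can therefore stand for 0 tags or for 1 tag, and genes that cells of every kind use are among them, so such a gene is called listed at 0 and its log2 values, which rest on the added 1, are not read as folds. A tag was worth 0.163 to 0.172 RPM. The sums of the columns were 186231, 151859, 115679 and 149969 RPM in the order 932 control, 932 heat, HY control and HY heat. The 20 most abundant genes held 48.7%, 40.5%, 35.0% and 37.1% of those sums, and the highest single gene held 12.3%, 7.97%, 5.46% and 3.85%.

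Of the 5558 gene models, 391 were listed at 0 in all 4 libraries and 2616 were above 0 in all 4. The best hit was a silkworm protein for 1087 models and a monarch butterfly protein for 3509, and 102 models had no hit. Product names are those of the hits, so a name is that of a similar protein and not always of the gene itself. Symbols came from a RefSeq gene table of assembly ASM3026992v2 through the protein accession of the hit, which matched for 895 of 909 RefSeq protein hits. No coordinates are given, because the build of the gene models is not stated.

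Ratios were computed as log2 of the value plus 1, for heat over control in each variety, for 932 over HY under each condition, and as the difference of the heat responses (932 minus HY). A gene entered a comparison with at least 1 RPM in 1 of its libraries, and counted as higher or lower from 2-fold on. With 1 library per group there is no p-value. The exact conditional 95% interval (Clopper-Pearson) was computed for the ratio of tag numbers. A total of 33 gene lists was fixed by product name patterns before the data were examined, and matches that are another protein were kept. For lists with at least 5 genes above the floor, the median was placed among the medians of 10000 random lists of the same size, matched on 10 bins of mean expression. Such a percentile describes these libraries.

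The genes named came from the 10 highest and the 10 lowest ratios of each comparison and of the difference. Only genes with at least 3 RPM in 1 library were ranked. Genes without a product name kept their rank there and were not named. Up to 4 members with the greatest change from each list described, and heat shock proteins of every class, were also named. Alternatives set in advance were median-of-ratios size factors, centring on the median gene, no floor, a floor of 10, added values of 0.1 and 10, a 4-fold rule, intervals beyond 2-fold, Spearman correlation, the mean of a list, and totals without the 20 most abundant genes. Ratios of the tag numbers with 0.5 tag added and a floor of 10 tags, and lists without members that are plainly another protein, were added after the data had been seen. The design also allowed a second deposited unit, but only 1 unit was used here.

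The calculations were tested on simulated data, in which tags were drawn for the real genes at the real totals with 200 genes changed by known folds. For heat in 932, with 2623 genes above the floor, 87% of genes changed 4-fold and 96% of genes changed 8-fold passed the 2-fold rule in the right direction. For heat in HY, with 2727 genes, these shares were 82% and 96%. Of the unchanged genes 17 of 2425 and 27 of 2530 passed by counting alone for heat in 932 and in HY, and none of the 828 and 894 with at least 10 RPM did. For 932 over HY 32 of 2475 passed under control and 26 of 2669 under heat, with 1 of 810 and 0 of 913 at 10 RPM or more. Of 200 unchanged lists in each comparison, 1.5%, 2.5%, 3.5% and 6% fell outside the range of random lists, in the same order. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.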

Results

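Gene expression was measured by deep sequencing in the midgut of silkworm larvae (Bombyx mori) on day 2 of the fifth instar, the last larval stage. The larvae belonged to 932, a variety that the labels call heat-tolerant, and to HY, which they call heat-sensitive. In each variety 1 library came from control larvae and 1 from larvae exposed to high temperature. The temperature and the length of the exposure were not given in the sources used here. Each group held 1 library, so no difference below has a replicate check, and every comparison is between libraries. The table listed 5558 gene models with values in tags per 1000000 tags of each library (RPM), with no correction for gene length. The values were whole numbers of tags at library totals of 6139297 tags for 932 control, 5828615 for 932 heat, 5799073 for HY control and 6005742 for HY heat. The listed models took 18.6%, 15.2%, 11.6% and 15.0% of those tags, and the remaining tags were not analysed here. Genes were compared as the log2 ratio of the value plus 1, which understates the change of low genes. A gene was counted as higher or lower when that ratio reached 2-fold and the gene had at least 1 RPM in 1 of the libraries compared. Intervals in square brackets are exact 95% intervals of the log2 ratio of the tag numbers, without the added 1, and cover counting error only.

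The first comparison asked how the midgut of the heat-tolerant variety 932 responded to high temperature. Heat shock proteins, the chaperones that hold and refold damaged proteins, were among the 10 highest ratios. Hsp19.9 (BGIBMGA004540), a small heat shock protein, stood at 0.81 RPM in control and 43.9 after heat, a log2 ratio of 4.63 [4.51 to 7.39]. The 90-kDa heat shock protein gene Hsp90 (BGIBMGA004612) stood at 0.81 and 35.2, a log2 ratio of 4.32 [4.19 to 7.07]. Hsp23.7 (BGIBMGA004515) stood at 12.9 and 210.3, a log2 ratio of 3.93 [3.70 to 4.38]. Of the 5 small heat shock protein genes above the floor, 4 were at least 2-fold higher and none lower, and the median log2 ratio of the list was 1.69, at percentile 100 of 10000 random lists matched on expression. The gene at that median was listed at 0 in control, so the median rests on the added 1 and is not read as a fold. The median of the list was 4.02 with 0.1 added in place of 1. The exception, Hsp21.4 (BGIBMGA000944), read 72.3 in control and 55.4 after heat. In the HSP70 list, which took in binding partners by name, 2 of 7 genes were higher and 1 lower, and the median was 0.13. The higher genes were the hsp70 binding protein BGIBMGA013070 from 6.68 to 40.7 and heat shock protein 70-3 (BGIBMGA007950) from 13.2 to 39.8. The abundant cognate Hsc70-4 (BGIBMGA002381) read 746 in control and 1144 after heat, a log2 ratio of 0.62. Heat shock protein 60 (BGIBMGA007349), a mitochondrial chaperonin, rose from 1.63 to 4.63. The BAG-domain co-chaperone Samui (BGIBMGA006976) rose from 0.33 to 3.95.

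**Figure D1:**
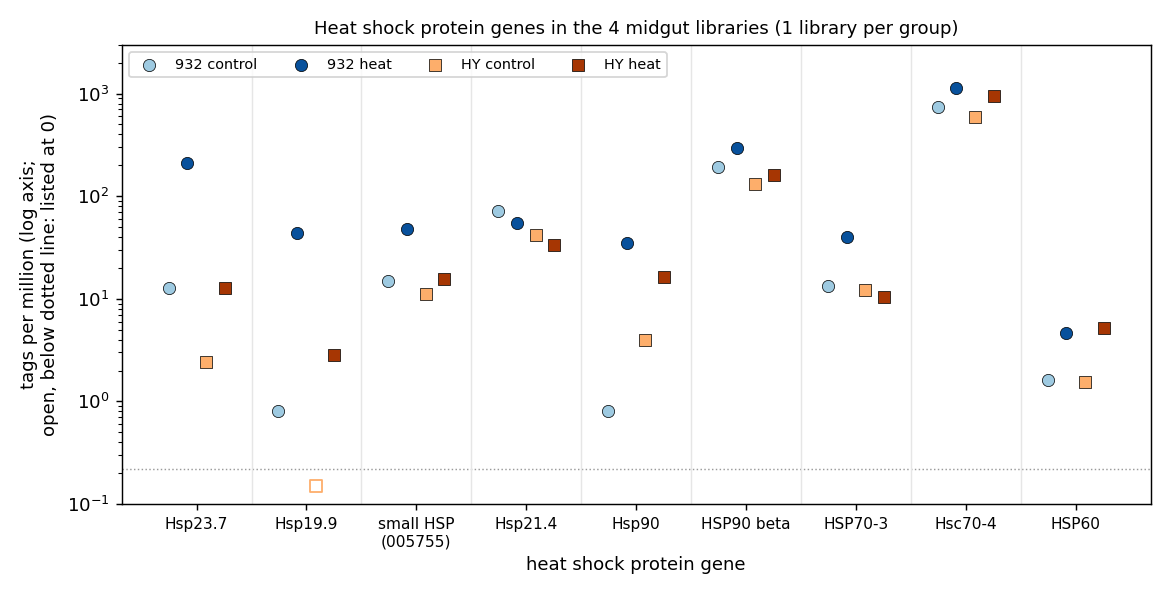
RPM (log axis) of 9 heat shock protein genes in the 4 midgut libraries, with circles for 932 and squares for HY, light for control and dark for heat, and 1 library per group, so no error bar can be drawn. Hsp23.7 read 12.9 in 932 control and 210.3 in 932 heat, against 2.41 and 12.7 in HY, while Hsp21.4 was slightly lower after heat in both varieties.

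The lists of proton pump and mitochondrial respiratory chain genes had medians below 0 in 932 after heat. V-ATPase subunits, which form the proton pump that energises the midgut epithelium, were at least 2-fold lower in 8 of 10 genes, with a median log2 ratio of -1.63 at percentile 0 of random lists. The accessory subunit S1 (BGIBMGA014403) went from 159 to 32.4, subunit E (BGIBMGA010247) from 168 to 36.0 and catalytic subunit A (BGIBMGA008295) from 31.6 to 6.86. In the list of mitochondrial respiratory chain and ATP synthase genes 14 of 40 were lower and none higher, with a median of -0.77 at percentile 0. That list took in V-ATPase genes by name. Without them 8 of 32 were lower, with a median of -0.70. The gamma subunit of ATP synthase (BGIBMGA013965) read 145 in control and 34.1 after heat, and mitochondrial cytochrome c (BGIBMGA009012), an electron carrier outside the list, read 204 and 30.5. Proteasome subunits had a median of -0.52 (percentile 1.05), with 2 of 16 at least 2-fold lower.

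The median of peritrophic matrix genes, whose products line the gut lumen, was also below 0 in 932 after heat. Of 9 such genes 4 were lower and 1 higher, with a median of -0.97 at percentile 0.05. Peritrophin 1 (BGIBMGA001504) read 60.9 in control and 12.9 after heat, the insect intestinal mucin IIM1 (BGIBMGA001480) read 168 and 38.95, and the peritrophic membrane chitin binding protein 1 (BGIBMGA001491) read 6170 and 1982. Trypsin and chymotrypsin-like serine proteases, which digest food protein, were lower in 10 of 31 genes and higher in 2, with a median of -0.43 at percentile 0.60, or -0.76 with a floor of 10 RPM. The trypsin gene BGIBMGA001320 fell from 534 to 168. A triacylglycerol lipase (BGIBMGA010400) was the most abundant gene of the control library and fell from 22884.5 to 3229, a log2 ratio of -2.82 [-2.85 to -2.80], but the lipase list as a whole had a median of 0.06, with 1 of 15 genes higher and 1 lower. Further low ends of the ranking were beta-1,3-glucan recognition protein 4 (BGRP4, BGIBMGA000353), a pattern recognition gene, from 321 to 15.4, and beta-galactosidase (Gal, BGIBMGA006815) from 70.4 to 8.06. MG7 (BGIBMGA011598) fell from 672 to 91.3, transferrin (BGIBMGA012221), an iron carrier, from 19.4 to 1.72, and a microtubule-associated protein named futsch (BGIBMGA007208) from 128 to 18.2.

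Antimicrobial peptide, lysozyme and peptidoglycan recognition genes were higher in 932 after heat in 4 of 6 genes, with a median of 1.28 at percentile 99.99. Lysozyme (Lzm, BGIBMGA010439), which cleaves bacterial cell walls, read 7 in control and 25.7 after heat, and PGRP-S1 (BGIBMGA008038) read 15.2 and 33.8. Moricin I (BGIBMGA011495) was listed at 0 in control and read 1.72 after heat. Ribosomal protein genes had a median of 0.11 at percentile 99.58 (0.21 with totals without the 20 most abundant genes, and a mean of 0.21), with 4 of 73 higher, among them RpL22 (BGIBMGA006986) from 272 to 925. In all, 300 of 2708 genes above the floor were at least 2-fold higher and 267 at least 2-fold lower, and the median log2 ratio of all genes was 0.02. For 107 and 95 genes the whole counting interval lay beyond 2-fold. Simulated libraries of these depths, with no difference in 2425 of the genes above the floor, put 17 of those past 2-fold by counting alone.

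The same comparison in the heat-sensitive variety HY showed digestive lipase and peritrophic matrix genes higher after heat. Lipases were at least 2-fold higher in 7 of 13 genes and lower in 1, with a median log2 ratio of 1.57 at percentile 100 of random lists. That median was 0.37 with no floor, 2.97 with a floor of 10 RPM and 2.53 without the phospholipases that the list took in by name, where 7 of 11 were higher. Intestinal lipase 6 (BGIBMGA002669) rose from 60.7 to 1075, the neutral lipases BGIBMGA001508 and BGIBMGA001507 from 60.2 to 687 and from 0.69 to 25.1, and an acidic lipase (BGIBMGA011777) from 0.69 to 38.0. Peritrophic matrix genes were higher in 6 of 10 and lower in 2, with a median of 1.64 at percentile 100, which was 0.58 with a floor of 10 RPM, and the mean was 0.79. With that floor the median of all genes was 0.43. IIM1 rose from 3.10 to 26.5, and a peritrophin type-A domain gene (BGIBMGA008863) was listed at 0 in control and read 5.83 after heat. The chitin binding domain 3 gene (BGIBMGA009067) of the same list went the other way, from 395 to 17.0.

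The library labelled HY heat was higher than HY control for 1940 of 2810 genes above the floor, with a median log2 ratio of 0.34 over these genes. Relative to that median the lipase list stood at 1.24 and the peritrophic matrix list at 1.31. With a floor of 10 RPM the peritrophic matrix list was only slightly above all genes. Serine proteases had a median of 0.54 at percentile 96.2, inside the range of random lists, or 0.20 relative to all genes, with 10 of 32 higher and 3 lower. Without inhibitors that the list took in by name 9 of 25 were higher and 3 lower, with a median of 0.64. The trypsin-like proteinase BGIBMGA003605 rose from 57.4 to 768, serine protease 36 (BGIBMGA008515) from 6.38 to 52.3 and a silk gland derived serine protease (BGIBMGA004445) from 1.03 to 29.1, while trypsin BGIBMGA001320 fell from 130.2 to 20.15. Aminopeptidases and carboxypeptidases, which complete protein digestion, were lower in 11 of 23 genes and higher in 3, with a median of -0.80 at percentile 0, or -1.14 relative to all genes and -0.42 with no floor. The carboxypeptidase BGIBMGA004798 read 15.4 in control and 1.5 after heat, and an aminopeptidase P-like gene (BGIBMGA001640) read 8.28 and 0.67. Midgut carboxypeptidase A1 (BGIBMGA009478) was among the higher members, from 0.86 to 12.7. V-ATPase genes had a median of -0.45 at percentile 0.09, with 1 of 10 lower, or -0.79 relative to all genes. Mitochondrial respiratory chain genes had a median of -0.00 at percentile 1.02, with none of 40 past 2-fold, or -0.34 relative to all genes, and the unshifted median was 0.04 with a floor of 10 RPM.

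Part of the heat shock genes were higher in HY as well. Hsp23.7 read 2.41 in control and 12.7 after heat, a log2 ratio of 2.00 [1.56 to 3.33], and Hsp90 read 3.97 and 16.3, a ratio of 1.80 [1.37 to 2.76]. Hsp19.9 was listed at 0 in control and read 2.83 after heat. The small heat shock protein list had 2 of 5 genes higher and a median of 0.47 at percentile 68.2, which is inside the range of random lists. The HSP70 list had 2 of 8 genes higher and none lower, with a median of 0.61 at percentile 87.7, also inside that range, or 0.28 relative to all genes. Heat shock protein 70-14 (BGIBMGA006574) rose from 5.52 to 15.3 and heat shock protein 60 from 1.55 to 5.16, while heat shock protein 70-3 read 12.2 and 10.3. Centred on the median gene, none of the HSP70 or HSP60 list members was 2-fold higher in HY. Hsc70-4 read 596 in control and 946 after heat. DnaJ-4 (BGIBMGA006824), an HSP40 co-chaperone, rose from 0.34 to 2.83. The endoplasmic reticulum chaperone calreticulin (BGIBMGA000475) fell from 10.2 to 2.33.

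Among the other ends of the HY ranking, beta-galactosidase rose from 6.38 to 176.5, BGRP4 from 1.72 to 44.1 and integument esterase 2 (ie2, BGIBMGA009544) from 1.90 to 34.8. A cuticle protein, CPH45 (BGIBMGA004124), fell from 1902 to 57.3, a log2 ratio of -5.03 [-5.21 to -4.90]. Allatostatin A (AST-A, BGIBMGA014377), a gut and brain neuropeptide, fell from 22.4 to 1.67, and Rel (BGIBMGA014594), an NF-kappa-B factor of insect immunity, from 14.3 to 1.67. An amino acid transporter (+nsd-2, BGIBMGA007228) read 103 in control and 15.98 after heat, and an L-asparaginase (BGIBMGA007025) read 36.9 and 4.5. Lebocin-3 (Leb3, BGIBMGA006775), an antimicrobial peptide, rose from 1.90 to 29.0, although its list had a median of -0.16. A fatty acid binding protein (BGIBMGA012890) rose from 5.35 to 51.1. In all, 397 genes were higher and 129 lower, so 75.5% of the 2-fold genes were higher. This split depended on the scaling: centred on the median gene, 127 were higher and 242 lower (34.4% higher), and with median-of-ratios factors 169 and 191. Whole counting intervals lay beyond 2-fold for 116 higher and 54 lower genes.

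**Figure D2:**
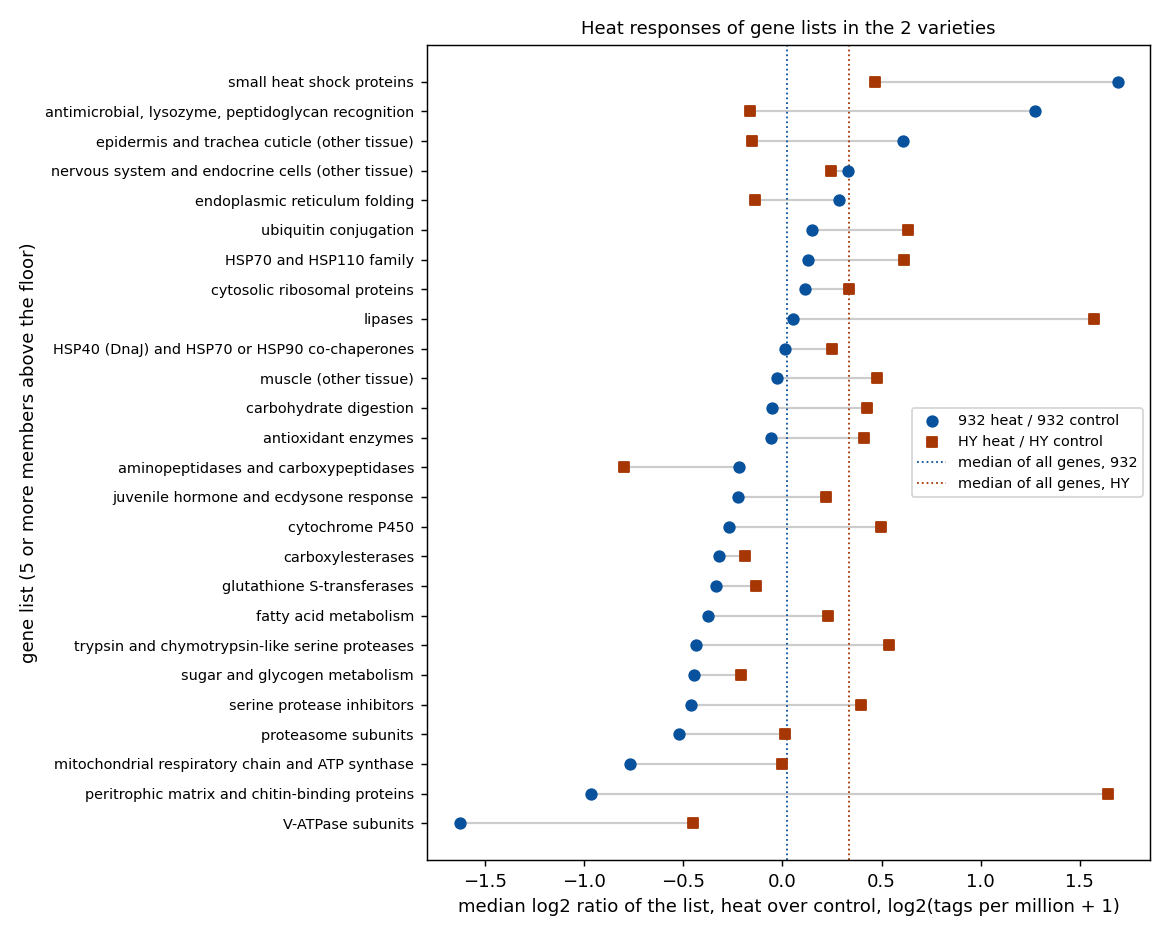
Median log2 ratio of heat over control for each gene list with 5 or more members above the floor in both varieties, with circles for 932, squares for HY and dotted lines at the median of all genes (0.02 in 932 and 0.34 in HY). The peritrophic matrix list lies at -0.97 in 932 and 1.64 in HY, and the V-ATPase list lies lowest in 932, at -1.63.

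The third question was whether the heat responses of the varieties differed. Across 3214 genes above the floor in any library the log2 responses of 932 and HY had a Pearson correlation of 0.11 and a Spearman correlation of 0.18. These are correlations across genes, which are not independent replicates, and the responses share no library. Both varieties had 59 genes higher, against 37.1 for independent lists of those sizes, and 17 lower, against 10.7. There were 12 genes higher in 932 and lower in HY, against 12.04, and 27 lower in 932 and higher in HY, against 32.98. The response was at least 2-fold greater in 932 for 260 genes and at least 2-fold smaller for 605, with a median of -0.25. This split also depended on the scaling, with 459 and 333 genes after centring and 404 and 385 with totals taken without the 20 most abundant genes.

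Small heat shock proteins had the greater response in 932, with 4 of 5 genes at least 2-fold apart and a median difference of 1.80 at percentile 100. That difference was 1.18 with 0.1 added, 1.18 with tag numbers and 0.93 with 10 added. Among the 4 genes Hsp19.9 was listed at 0 in HY control, and the gene at the median was listed at 0 in 932 control. Their places there, and the median difference, therefore rest on the added 1. Hsp19.9 and Hsp23.7 read 43.9 and 210.3 in 932 heat and 2.83 and 12.7 in HY heat. The HSP70 list had a median difference of -0.34 at percentile 41.2, inside the range of random lists, with 2 of 8 genes greater in 932 and 2 smaller. The antimicrobial and recognition list had a median difference of 1.59 at percentile 100, with 5 of 7 genes greater in 932 and 1 smaller. Peptidases had a median difference of 0.44 at percentile 99.99, with 10 of 27 greater and 5 smaller. Peritrophic matrix genes had the smaller response in 932 in 7 of 10, with a median difference of -2.58 at percentile 0. The mean of that list was -1.48. V-ATPase genes had a median of -1.18 at percentile 0.16, which was -0.69 with no floor. Mitochondrial respiratory chain genes had -1.03 at percentile 0, or -0.89 without V-ATPase genes, -0.66 with totals without the 20 most abundant genes and -0.56 with 10 added. Lipases had -0.94 at percentile 0.61, or -1.52 without phospholipases, and serine proteases had -0.63 at percentile 1.48. With each response centred on the median gene of its variety these differences were 2.12 for small heat shock proteins, 0.76 for peptidases, -2.26 for peritrophic matrix genes, -0.86 for V-ATPase genes, -0.71 for mitochondrial genes, -0.63 for lipases and -0.31 for serine proteases. Some genes at the ends of this ranking went opposite ways. BGRP4 fell from 321 to 15.4 in 932 and rose from 1.72 to 44.1 in HY, and the 30-kDa lipoprotein Lp-c6 (BGIBMGA004394), a storage protein, was listed at 0 in 932 control and HY heat and read 10.47 in 932 heat and 9.48 in HY control. The cuticle protein CPH45, also at the upper end, was lower after heat in both, from 1322 to 896 in 932 and from 1902 to 57.3 in HY. These differences were not tested, since each response rests on 1 pair of libraries.

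Under control conditions the varieties differed in some lists of digestive, detoxification and immune genes. Peptidases (median 0.16, percentile 62.6), carbohydrate digestion (0.69, 96.6), cytochrome P450 (0.20, 66.8) and glutathione S-transferases (-0.84, 3.23) lay inside the range of random lists. Lipases were at least 2-fold higher in 932 in 10 of 15 genes and lower in 3, with a median log2 ratio of 2.35 at percentile 100, which was 0.93 with no floor. The triacylglycerol lipase read 22884.5 in 932 and 470.4 in HY, and the neutral lipase BGIBMGA001508 read 2182 and 60.2. Serine proteases were higher in 932 in 16 of 33 genes and lower in 6, with a median of 0.88 at percentile 99.99. Without inhibitors that the list took in by name 16 of 28 were higher and 3 lower, with a median of 2.09, and the median of the whole list was 2.14 with a floor of 10 RPM and 0.41 with 10 added. Trypsin-like proteinase BGIBMGA003605 read 1499.7 in 932 and 57.4 in HY. UDP-glycosyltransferases, which conjugate plant and other foreign compounds, had a median of 2.87 at percentile 99.99, with 4 of 6 higher and 2 lower, and with no floor the median was 0.41. UGT33D7 (BGIBMGA013861) read 7.49 in 932 and was listed at 0 in HY, while UGT33D5 (BGIBMGA013860) was listed at 0 in 932 and read 13.1 in HY. Whether tags were shared between such members of a family was not measured. Sugar transporters were higher in 932 in 5 of 6, with a median of 1.58 at percentile 99.84 (0.94 with no floor), and carboxylesterases in 4 of 8 and lower in 1, with a median of 0.99 at percentile 98.4.

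V-ATPase genes were higher in 932 control than in HY control in 7 of 10, with a median of 1.13 at percentile 99.86. The control libraries compared here are also those of the heat responses. A list that differed here and in a heat response is therefore not a separate result, since an unusual control library would appear in both. Subunit G (BGIBMGA013678) read 2196 in 932 and 742 in HY. Mitochondrial respiratory chain genes were higher in 15 of 40, with a median of 0.66 at percentile 99.92, and without the V-ATPase genes of that list in 9 of 32, with a median of 0.58. The median of the whole list was 1.03 with a floor of 10 RPM and 0.42 with totals without the 20 most abundant genes. Peritrophic matrix genes were higher in 4 of 9 and lower in 1, with a median of 0.98 at percentile 98.9. Antimicrobial and recognition genes were lower in 932 in 5 of 7, with a median of -1.54 at percentile 0.02. Peptidoglycan recognition protein S6 (BGIBMGA012866, whose hit has the symbol PGRP-S5) read 1.14 in 932 and 619 in HY. Serine protease inhibitors were lower in 932 in 5 of 7, with a median of -1.03 at percentile 0.84, and serpin-5 (BGIBMGA013849) read 3.42 and 56.6. RpL32 (BGIBMGA000066), a ribosomal protein gene, was listed at 0 in 932 and read 788 in HY, while the ribosomal list as a whole had a median of 0.07 and 3 of 74 genes lower. Srp9 (BGIBMGA001186), a subunit of the signal recognition particle, read 90.2 in 932 and was listed at 0 in HY. Of 2780 genes above the floor 499 were higher in 932 and 419 lower, with a median of 0.05, and 281 and 217 had whole counting intervals beyond 2-fold. With totals taken without the 20 most abundant genes the split turned to 386 and 568.

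**Figure D3:**
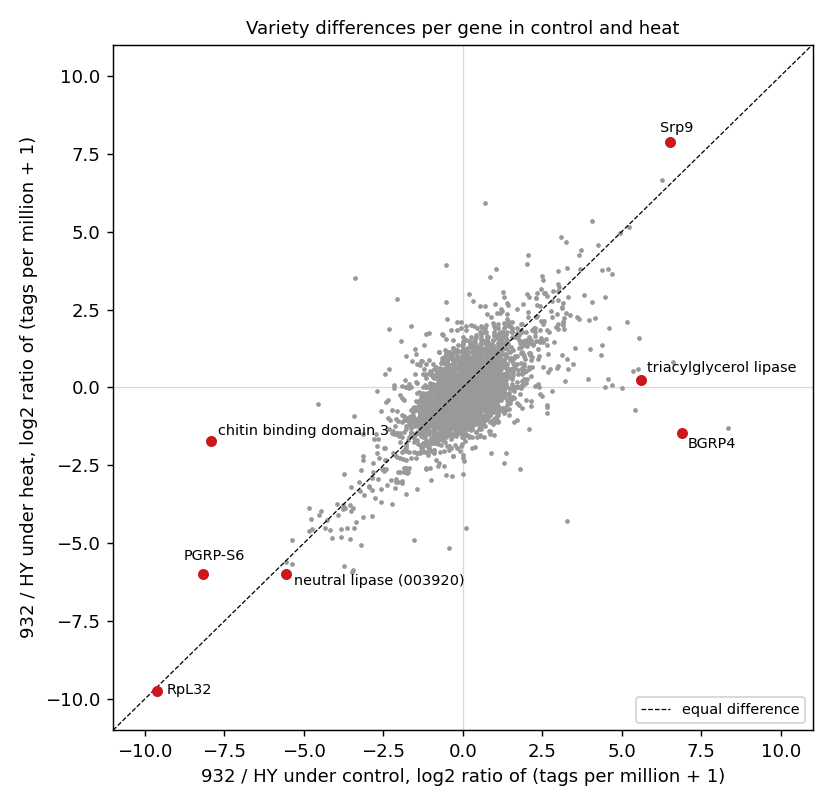
Log2 ratio of 932 over HY under control (horizontal) and under heat (vertical) for the 3214 genes with at least 1 RPM in any library, 1 point per gene, with equal differences on the dashed line. The neutral lipase BGIBMGA003920, with 3.09 and 2.40 RPM in 932 against 192 and 217 in HY in the order control and heat, lies near the line, whereas BGRP4 (BGIBMGA000353) stands at 6.89 under control and -1.46 under heat; values of genes listed at 0, such as RpL32 and Srp9, rest on the added 1.

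After heat the varieties still differed in many of the same genes, but not in all of the same lists. The medians of 932 over HY were then -0.02 for V-ATPase genes, -0.15 for mitochondrial, -0.46 for peritrophic matrix and 0.07 for antimicrobial and recognition genes, at percentiles 74.4, 53.9, 25.6 and 79.1, all inside the range of random lists. The variety differences under control and under heat had a Pearson correlation of 0.65 and a Spearman correlation of 0.54 across 3214 genes, with no library in common. At least 2-fold higher in 932 under both conditions were 215 genes, against 65.4 for independent lists, and 241 were lower under both, against 81.0. RpL32 read 0.34 in 932 heat and 1138 in HY heat, and Srp9 read 236 in 932 and was again listed at 0 in HY. A neutral lipase (BGIBMGA003920) read 2.40 in 932 and 217 in HY, an HSP70-interacting protein (BGIBMGA010635) read 2.23 and 158, and an inward rectifier potassium channel (BGIBMGA013821) read 1.89 and 146. Neuropeptide F 1 (NPF1, BGIBMGA006281), a feeding-related peptide, read 23.0 in 932 and was listed at 0 in HY. Hemolin (BGIBMGA008736), an immune protein of moths, read 0.51 in 932 and 87.1 in HY.

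Small heat shock proteins were higher in 932 heat than in HY heat in 3 of 5 genes and lower in none, with a median log2 ratio of 1.55 at percentile 99.7. The median of the HSP70 list went the other way, at -1.06 and percentile 0.93, with 4 of 8 genes lower and 2 higher. With a floor of 10 RPM that median was 0.27. Without the binding partners taken in by name, 2 of 5 genes were lower and 1 higher, with a median of -0.998. Centred on the median gene, 3 genes of the whole list were lower and 2 higher, with a median of -0.80. The HSP70-interacting protein BGIBMGA010635 was already lower in 932 under control, at 1.95 against 138 in HY. The whole list summed to 1236 RPM in 932 heat and 1151 in HY heat. Peptidases were higher in 932 in 12 of 26 and lower in 2, with a median of 0.69 at percentile 99.99, and aminopeptidase N-5 (BGIBMGA008063) read 198.5 in 932 and 6.83 in HY. UDP-glycosyltransferases (median 1.84, 5 of 7 higher and 2 lower), carboxylesterases (1.12, 6 of 9 higher and 2 lower), lipases (0.83, 6 of 15 higher and 2 lower) and carbohydrate digestion genes (0.77, 5 of 12 higher and none lower) were above the range of random lists. With no floor the medians of the UDP-glycosyltransferases, carboxylesterases and lipases were each 0.42. Relative to the median of all genes small heat shock proteins stood at 1.81, lipases at 1.09 and peptidases at 0.95. Of 2990 genes above the floor 421 were higher in 932 and 621 lower, with a median of -0.26. Centred on the median gene the split was 534 and 352, and with median-of-ratios factors it was 506 and 384.

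Markers of tissues that a dissected midgut could carry along were read beside these lists. The 14 muscle genes had medians of -0.03 for heat in 932 and 0.48 for heat in HY, where the median of all genes was 0.34, and 0.31 for 932 over HY under control. Cuticle genes of epidermis and trachea had a median of 0.61 for heat in 932 and -0.16 for heat in HY. In 4 of 8 the response was at least 2-fold greater in 932. The median difference was 1.22 at percentile 99.98, above the range of random lists, and -0.32 with no floor. For 932 over HY under heat their median was 0.85 at percentile 97.58, slightly above that range. The cuticle genes summed to 2713 and 3811 RPM in 932 and to 3494 and 1489 in HY, in the order control and heat. CPH45 (BGIBMGA004124) read 1322 and 896 in 932 and 1902 and 57.3 in HY, and CPH43 (BGIBMGA005302) read 297 and 1227 in 932 and 743 and 682 in HY. Nervous system and endocrine genes had medians of 0.33 and 0.24 for heat in 932 and HY. Fat body storage, hemocyte and silk gland lists had fewer than 5 genes above the floor, and their summed values were at most 54.7 RPM in any library.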

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

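All tests of explanations in this part were chosen after the results had been seen. The items below are those genes covered by the rule for named genes, and those lists, that went at least 2-fold up after heat in 1 variety and at least 2-fold down in the other or, for a list, had medians of opposite sign that both lay outside the range of random lists. Each difference rests on 1 library per group and was not tested. Values are the log2 response in 932 minus that in HY.

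Peritrophic matrix and chitin-binding proteins differed by -2.58 as a list. With a floor of 10 RPM the HY median of that list was only slightly above that of all genes. BGRP4 (BGIBMGA000353) differed by -8.34, beta-galactosidase (Gal, BGIBMGA006815) by -7.57, MG7 (BGIBMGA011598) by -5.79 and the triacylglycerol lipase (BGIBMGA010400) by -5.35. The hatching enzyme-like gene Hel (BGIBMGA007915) differed by -5.03, the silk gland derived serine protease (BGIBMGA004445) by -4.95, the mucin IIM1 (BGIBMGA001480) by -4.83 and integument esterase 2 (BGIBMGA009544) by -4.72. The futsch gene (BGIBMGA007208) differed by -4.61 and peritrophin 1 (BGIBMGA001504) by -3.96. In the other direction the venom acid phosphatase gene (BGIBMGA006176) differed by 4.22, storage protein Sp2 (BGIBMGA009028) by 4.91, the chitin binding domain 3 gene (BGIBMGA009067) by 6.19 and Lp-c6 (BGIBMGA004394) by 6.91. Integument esterase 2 was listed at 0 in 932 heat, and Lp-c6 in 932 control and HY heat, so their values rest on the added 1. Of all genes above the floor, 27 went down in 932 and up in HY and 12 went up in 932 and down in HY, against 32.98 and 12.04 for independent lists of those sizes.

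For the opposite responses of the peritrophic matrix list, a few genes taking most of the counts were tested by taking totals without the 20 most abundant genes. The list then stood at 1.42 in HY and -0.87 in 932. Such totals shift all genes of a comparison by nearly the same amount. The median of all genes went from 0.34 to 0.12 in HY and from 0.02 to 0.09 in 932. The prediction was written after this shift had been seen, so no conclusion is drawn from it. The values show only that the shift was small beside the medians of the list. Swapped control and heat labels in 1 variety would put heat shock genes down in the library labelled HY heat, but the 3 heat shock proteins among the highest genes of 932 heat had a median of 1.94 there, which is the value of Hsp19.9 and rests on the added 1, and Hsp90 and Hsp23.7 stood at 1.80 and 2.00, with counting intervals above 0. More muscle in the HY control dissection would put the muscle list well below 0 for 932 over HY, and it stood at 0.31. Other carried-over tissue stays open. The cuticle list stood at -0.41 for 932 over HY under control, at percentile 9.04 and inside the range of random lists. Its sum fell from 3494 to 1489 RPM in HY after heat, mostly through CPH45, which went from 1902 to 57.3. An untested difference in feeding, growth or handling of the animals in 1 library also stays open, beside a response that differs between the varieties.

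The small heat shock protein list had a greater response in 932. Different scaling of the libraries was examined by centring each response on its median gene, which gave a median difference of 2.12. Centring moves every gene of a response by the same amount, set by all-gene medians of 0.02 in 932 and 0.34 in HY. The outcome followed from these medians, so no conclusion is drawn from it. The values show only that this shift was small beside the difference and raised it. The size of the difference moved with the added value (1.18 with 0.1 and 0.93 with 10), and the gene at its median was listed at 0 in 932 control. A higher starting level in HY would bring HY to the level of 932 after heat, but 932 over HY stood at 1.55 there, and at 0.58 under control. The variety itself, which the labels name, and a difference between the animals, or the exposure, of single libraries stay open.

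Genes such as RpL32 and Srp9 were near 0 in 1 variety and abundant in the other. Of 46 genes 16-fold apart under control, 29 (63.0%) were at least 4-fold apart the same way under heat and 17 were not 4-fold apart. The 46 were chosen by fold alone, and 11 of them were listed at 0 in 1 variety in both conditions. A sequence variant in the counted stretch of the transcript could stand behind part of the 29. For these it cannot be told apart from a difference in expression, because either could give the same direction in both conditions. Of the genes still 4-fold apart, 0% went the opposite way, which argues against swapped variety labels of 2 libraries.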

How the results depend on the processing

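The ratios of tag numbers with 0.5 tag added and the lists without members that are another protein were chosen after seeing the data, and the other settings before. With no floor the counts of the 4 comparisons cannot move, because a gene under 1 RPM cannot reach 2-fold after 1 is added. Counts of 2-fold genes are given in the order heat in 932, heat in HY, 932 over HY under control, 932 over HY under heat and difference of the responses, against main counts of 567, 526, 918, 1042 and 865. A floor of 10 RPM gave 230, 205, 360, 394 and 346, by fewer genes entering. An added value of 10 gave 90, 82, 223, 210 and 163, and the 4-fold rule 53, 63, 259, 239 and 129, by construction. An added value of 0.1 gave 930, 859 and, for the difference, 1452. Counting intervals beyond 2-fold gave 202, 170, 498 and 516 for the 4 comparisons. Size factors, centring and the other totals kept every count within 1.5 times, but turned splits in every comparison and in the difference. The share of 2-fold genes that were higher was 52.9% for heat in 932 and turned to 49.1% with median-of-ratios factors, 49.3% after centring, 48.7% with the floor of 10 and 40% with 10 added, and it was 61.1% with totals without the 20 most abundant genes. For heat in HY it was 75.5% and turned to 46.9% with median-of-ratios factors and 34.4% after centring, and it was 54.8% with totals without the 20 most abundant genes. For 932 over HY under control it was 54.4% and turned to 40.5% with those totals. Under heat it was 40.4% and turned to 56.9% with the factors and 60.3% after centring. For the difference it was 30.1%, 47.8% with the factors, and turned to 58.0% after centring and 51.2% with those totals. The correlation of the responses was 0.11, 0.06 (0.0562) with 0.1 added and 0.18 by Spearman. The cause of these shifts was not tested. Of 141 list medians 46 lay outside the range of random lists, and 31 to 49 did under the alternatives, the lowest with the floor of 10, where 88 medians could be placed. Of 444 alternative values of those 46 medians, 438 kept their sign. The exceptions were the HSP70 list under heat (0.27 with the floor of 10), the mitochondrial list for heat in HY (0.037 with no floor, 0.0429 with the floor of 10, 0.043 with tag numbers and 0.0479 without other proteins, against -0.00) and the cuticle list for the difference (-0.32 with no floor); the cause was not tested. With 10 added many medians shrank, by construction, such as V-ATPase for heat in 932 (-0.49) and the peritrophic difference (-0.93). Other units could not be compared, since 1 was used. No paired analysis was made. Each comparison made sets 1 library against 1 library, and no result comes from a test. Depth limits genes under 10 RPM most, where counting alone puts some unchanged genes past 2-fold.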

Other observations

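Other gene groups were read in the same way. Cytochrome P450 genes went both ways within each comparison: Cyp9a20 (BGIBMGA003945) read 80.5 in 932 control, 32.9 in 932 heat, 4.14 in HY control and 6.49 in HY heat, and Cyp6ab5 (BGIBMGA012089) read 4.72, 3.09, 48.3 and 43.8 in that order. Among glutathione S-transferases, GSTe2 (BGIBMGA002279) was listed at 0 in both 932 libraries and read 17.1 and 22.6 in HY control and heat, and GSTo4 (BGIBMGA011820) fell from 36.8 to 9.09 in 932. Antioxidant enzymes had medians of -0.06 for heat in 932 and 0.41 in HY, and superoxide dismutase (SOD, BGIBMGA001307) read 0.65 and 3.77 in 932 and 1.03 and 1.5 in HY. A ferritin gene (BGIBMGA008768), for iron storage, read 306 and 342 in 932 and 54.3 and 37.3 in HY. Ubiquitin conjugation genes had medians of 0.15 in 932 and 0.63 in HY, and polyubiquitin (BGIBMGA001549) read 143 and 198 in 932.

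Of genes of juvenile hormone and ecdysone response most were within 2-fold between 932 and HY after heat, but the list had a median of 0.66 at percentile 99.7, or 0.42 with no floor, and 4 of 14 genes at least 2-fold higher in 932. Juvenile hormone diol kinase (Jhdk, BGIBMGA008814), a hormone-degrading enzyme, read 833 in 932 heat and 395 in HY heat. Sugar and glycogen metabolism had medians of -0.44 and -0.21 for heat in 932 and HY, with none of 8 genes past 2-fold in either. The HY median lay at percentile 2.03, below the range of random lists. Relative to all genes it was -0.55, with 3 genes 2-fold lower. Fatty acid metabolism had medians of -0.38 and 0.23. For the co-chaperone list the medians were 0.01 and 0.25, and under control 932 stood above HY with a median of 0.70 but a mean of 0.38, a median of 0.13 with 10 added, and 3 of 14 genes higher and 1 lower. There DnaJ-3 (BGIBMGA003153) read 15.3 in 932 and 1.03 in HY. Neuropeptide F 2 (NPF2, BGIBMGA009803) read 9.77 and 12.2 in 932 control and heat and 0.34 in HY control, and was listed at 0 in HY heat.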
